A study of Mus musculus with 7 samples.

How the data were processed

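Single-cell libraries of mouse aorta were analysed, 3 from flox control and 4 from endothelial knockout samples, all on a high-salt diet for 3 weeks. Groups were taken from the genotype label, and libraries are numbered as in their names, since the label of flox control 2 carries a replicate number that conflicts with its name. Per the labels, the tissue was digested enzymatically with dispase, elastase, collagenases, DNase and hyaluronidase, and the cells were stained for viability with Calcein-AM and Draq7 before capture on the BD Rhapsody system. The deposited files hold raw UMI counts per gene and cell barcode, 1 matrix per library, with 31253 genes and no normalization by the authors. Per the submitters' processing notes, CASAVA 1.8, STARsolo 2.7.10a and Seurat were used with genome build mm10, and their roles, the gene annotation and the rule that selected barcodes are not given in the sources used here. Every deposited barcode had at least 500 UMIs in each library. Between 6167 and 13792 barcodes and between 22646246 and 73102988 UMIs per library stood behind the values. Gene identifiers were matched to the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, for coordinates and gene spans only, and 99.78% of the identifiers matched.

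Cells with fewer than 200 detected genes or more than 25% of counts from mitochondrially encoded genes were removed. Doublets were called in each library with Scrublet in scanpy 1.11.5 (expected rate 0.06, automatic threshold), which removed 0.869% to 2.07% of cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1.0 (leidenalg 0.10.2), with all libraries together and no batch integration. This gave 26 clusters, of which 4 held 1 cell each. Clusters were named from marker genes fixed before the data were examined. The scoring rule was set after the data were seen: at least 3 markers detected in at least 20% of cells, a marker score of at least 0.25, at least 20 cells, no larger number of top genes from another class, and no cluster of low UMI count without its own markers among its top genes. Clusters are called by the cell type they resemble, and those that missed the rule stayed unnamed.

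UMI counts were summed per library over the cells of a class, since cells are not replicates, and each library entered a class with at least 20 cells of it. Endothelial-like cells numbered 122, 173 and 55 in the flox controls and 47, 182, 238 and 567 in the knockouts, with 150127 to 1832950 UMIs per library. Smooth muscle-like sums held 1494520 to 27297843 UMIs, fibroblast-like sums 12888652 to 40670553 and macrophage-like sums 547504 to 4238207. Genes were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood test) in R 4.3.3, with genotype as the term and Benjamini-Hochberg adjusted p under 0.05 as the threshold, in each of 4 main classes. Positive log2 fold changes mean higher in the endothelial knockout. The difference of the genotype effect between endothelial-like and smooth muscle-like cells was tested in edgeR as an interaction with the library as a block. Levels are given as CPM relative to the UMIs of the tested genes in the class and library times the TMM factor, as mean ± SD over libraries.

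Of 32 gene lists fixed before the data were examined, those with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a class. Those described cover amino acid transporters, the ATF4 amino acid response, nitric oxide signalling, vasoactive factors, endothelial activation, interferon response, endothelial to mesenchymal transition, smooth muscle contraction, collagen and matrix, growth factor beta signalling, hypoxia, NRF2 targets, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, macrophage inflammation, macrophage residency and repair, and the osmotic stress response. A list was described where it was called. In endothelial-like cells the lists of amino acid transporters, the ATF4 response, nitric oxide signalling, vasoactive factors and endothelial activation were described in any case. Other lists on the endothelium, such as angiogenesis, were tested but not described. The osmotic stress list is given beside Slc5a3, a gene named after its values were seen. Shares of kept cells were compared by exact two-sided permutation over the 35 splits of 7 libraries into 3 and 4.

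The genes named were set by a rule fixed before the data were examined. Slc38a2 is always named, and in each main class the 10 largest rises and falls among genes that pass with a mean of at least 4 log2 CPM and no overlap of the groups. Where fewer than 10 pass, the 10 with the smallest p and that mean are named and said not to pass. For each list described, up to 4 members with the smallest p are named. Predicted genes, immunoglobulin and T cell receptor segments, haemoglobin and sex-linked genes are left out unless a list holds them. Some genes that the rule takes are not reported here. Dgkb and Slc5a3, and Cmss1 and Cpeb1 in classes where the rule did not take them, were named after their values were seen, as were the other genes that moved the same way in all 4 classes.

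The tests were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed by 2-fold or 4-fold. Of the 2-fold changes 25% were recovered among 7416 genes in endothelial-like cells, 51% among 12636 in smooth muscle-like cells, 56% among 15294 in fibroblast-like cells, 31% among 10631 in macrophage-like cells and 26% among 10833 for the interaction. Of the 4-fold changes 84%, 90%, 88%, 96% and 61% were recovered. In the same order 7 of 116, 12 of 153, 13 of 157, 11 of 138 and 10 of 97 calls were false. A simulated list shifted by 1.5-fold passed camera in the 4 classes at the preset correlation. With an estimated correlation its adjusted p was 0.103 in endothelial-like, 0.00972 in smooth muscle-like, 0.00485 in fibroblast-like and 0.0151 in macrophage-like cells. The simulated genes were drawn independently, so the simulation cannot test the preset correlation for lists whose genes vary together. In the real endothelial-like sums the estimated correlation was 0.365 for oxidative phosphorylation, 0.332 for smooth muscle contraction and 0.592 for interferon response. Libraries of a group were checked for duplicates, and no pair agreed within counting noise.

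Alternatives fixed before the data were examined were RLE factors, no low count filter, DESeq2 1.42.0, limma-voom for the interaction, the replicate number as a block, a stricter cell filter (500 genes, 15% mitochondrial counts), doublets kept, Leiden resolution 0.5, classes assigned per cell, genes at least 5 times higher in another main class left out, an estimated correlation, fry, other denominators and scales for shares, and each library left out in turn. After seeing the data, the libraries with under 100 endothelial-like cells, and the fibroblast-like cluster led by Il6, were also left out. Reads of near-identical genes such as Rnaset2a and Rnaset2b can be shared, so their values are uncertain.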

Results

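Gene expression was measured cell by cell in the aorta of mice that ate a high-salt diet for 3 weeks. The question was how the vessel wall differs when endothelial cells, the inner lining of the artery, lose Slc38a2, which encodes SNAT2, a sodium-coupled transporter of neutral amino acids such as glutamine and alanine. Libraries came from 3 flox control samples, which carry Slc38a2 alleles flanked by recombination sites, and from 4 endothelial knockout samples. All 7 were prepared on the BD Rhapsody system, which captures single cells in microwells with barcoded beads and counts each transcript by a unique molecular identifier (UMI). Flox control libraries 1, 2 and 3 held 12625, 12614 and 6167 barcodes with 54442238, 61672130 and 22646246 UMIs. Endothelial knockout libraries 1, 2, 3 and 4 held 11326, 11821, 13792 and 8014 barcodes with 61096965, 64898597, 73102988 and 32941316 UMIs. After cell filtering 67477 of 76359 barcodes remained, with a median of 3085 to 5465.5 UMIs per cell between libraries. The labels do not say that the libraries came from separate animals, so all p-values measure the spread between these 7 libraries, which may in part be technical.

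By the group means of kept cells, fibroblast-like cells were the largest class in both genotypes, followed by smooth muscle-like, macrophage-like and endothelial-like cells. Single libraries departed from that order, with 39.8% smooth muscle-like against 37.5% fibroblast-like cells in knockout 3, and fewer smooth muscle-like than macrophage-like or endothelial-like cells in knockout 4. The endothelial-like cluster was led by Cytl1, Pecam1, Ptprb, Vwf and Edn1, and the larger smooth muscle-like cluster by Acta2, Tagln and Myh11, which encode contractile proteins. Macrophage-like cells were led by C3ar1, Mrc1, Folr2 and the complement genes C1qc and C1qb. Fibroblast-like cells formed 6 clusters, of which the largest was led by Fmod and Hhip, and 1 was led by the inflammatory genes Il6, Cxcl1, Ptgs2 and Lif. Smaller classes resembled T cells, B cells, monocytes, neutrophils, mast cells, erythroid cells and Schwann cells. A further 6849 cells (10.15%) stayed unnamed, among them a cluster with a median of 623 UMIs per cell led by Dmd and Ctnna3. The labels name goblet cells, which are mucus-secreting cells of epithelia, but 0 cells carried 3 or more of the 7 goblet markers, and Tff3 and Clca1 had 0 UMIs in all barcodes.

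The share of Slc38a2 UMIs that came from RNA of other cells was not measured. Slc38a2 (ENSMUSG00000022462, minus strand of chromosome 15 from 96687392 to 96699730, build GRCm38) was read in every library, also in endothelial-like cells. Its level there was 395 ± 44.9 CPM (SD, n = 3) in flox controls, where CPM is the UMI count relative to the UMIs of the tested genes in the class and library, scaled by the TMM factor, and 293 ± 59.8 CPM (SD, n = 4) in knockouts. Flox control libraries 1, 2 and 3 gave 446.7, 366.5 and 371.8 CPM from 170, 228 and 67 UMIs. Knockout libraries 1, 2, 3 and 4 gave 206.4, 301.8, 333.6 and 331.6 CPM from 31, 216, 341 and 534 UMIs, each below every flox control. The log2 fold change was -0.40 (SE 0.22), which did not pass edgeR's quasi-likelihood test across all genes (adjusted p = 0.789). In an exact two-sided permutation test of the CPM values p was 0.029, the smallest that 35 splits of 7 libraries can give, and 0.114 after adjustment over the 4 main classes. In smooth muscle-like cells Slc38a2 stood at 310 ± 65.3 CPM in flox controls and 291.5 ± 60.7 CPM in knockouts, with values of 273.2, 271.7 and 385.6 against 241.0, 261.6, 378.4 and 285.0 CPM. Fibroblast-like cells had 489 ± 93.4 CPM in flox controls, from 446.5, 424.7 and 596.3, and 372.6 ± 126 CPM in knockouts, from 218.7, 447.9, 499.3 and 324.4. Macrophage-like cells had 427 ± 97.0 CPM in flox controls, from 405.1, 343.0 and 533.1, and 314 ± 50.2 CPM in knockouts, from 254.1, 373.9, 328.0 and 300.1. The log2 fold changes in these classes were -0.09 (SE 0.19), -0.39 (SE 0.27) and -0.43 (SE 0.21), with adjusted p of 0.993, 0.958 and 0.680. The labels do not name the deleted exons, and the reads may lie at an end of the transcript outside them, so neither the level nor the change of Slc38a2 checks the genotype labels.

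**Figure D1:**
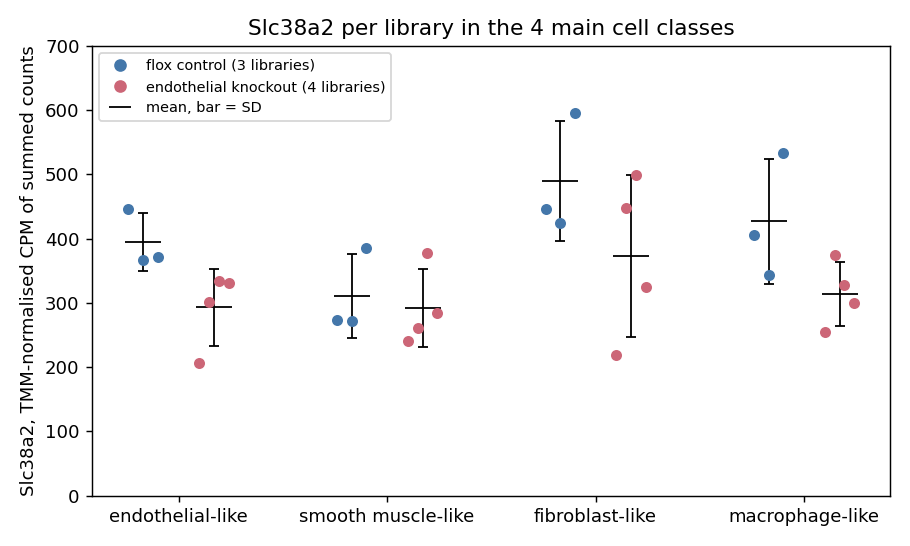
Slc38a2 level in CPM for the 4 main cell classes, with 1 point per library and mean ± SD bars for 3 flox control and 4 endothelial knockout libraries. In endothelial-like cells the knockout libraries lay between 206.4 and 333.6 CPM, below the flox controls at 366.5 to 446.7 CPM, while in the other classes the groups overlapped.

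In endothelial-like cells 1 gene passed the test, Dgkb, which encodes diacylglycerol kinase beta, an enzyme that converts the lipid messenger diacylglycerol to phosphatidic acid. Dgkb fell by 4.46 on the log2 scale (SE 0.59, adjusted p = 0.025, edgeR). It had 28.9, 35.4 and 44.4 CPM in the flox controls, from 11, 22 and 8 UMIs, against 0, 2.79, 0 and 1.86 CPM in the knockouts, from 0, 2, 0 and 3 UMIs. Dgkb (ENSMUSG00000036095) lies on the plus strand of chromosome 12 from 37817726 to 38634239, and its mean of 3.90 log2 CPM was under the minimum for named genes, so it was chosen after its values were seen. The next genes by p did not pass, at adjusted p of 0.560 to 0.609. Among them Nme1, a nucleoside diphosphate kinase, stood at 25.6 ± 6.70 CPM in flox controls (n = 3) and 66.6 ± 10.6 CPM in knockouts (n = 4). Cox17, a copper chaperone of cytochrome c oxidase, stood at 85.7 ± 3.79 and 162.6 ± 18.9 CPM, and Ndufc2, a subunit of respiratory complex I, at 66.9 ± 1.25 and 127.8 ± 27.3 CPM. Serpina1b, an antitrypsin gene with close copies that can share its reads, was also higher in knockouts (log2 fold change 1.45, SE 0.34). Lower values in knockouts were found for Rasl11b (-1.44, SE 0.30), the stress kinase gene Map3k5 (-1.69, SE 0.39), Phldb1 (-1.21, SE 0.29), Cmss1 (-1.72, SE 0.41) and Rptor, a scaffold of the growth kinase complex mTORC1 (-1.48, SE 0.36). Cmss1 overlapped between the groups, at 299.7 CPM in flox control 3 against 135.4 to 372.8 CPM in knockouts. Many of these genes had their highest level in another class. That was smooth muscle-like cells for Dgkb, Rasl11b, Cox17 and Ndufc2, macrophage-like cells for Nme1, Map3k5 and Rptor, and fibroblast-like cells for Phldb1. The share of their UMIs that came from RNA of other cells was not measured. Of 7416 genes tested, 471 had an unadjusted p under 0.05, where 370.8 would be so by chance, 209 of them higher and 262 lower in knockouts. Other splits of the same libraries gave up to 1000 such genes. DESeq2 called 2 genes, Dgkb among them. The values of the groups did not overlap for 551 genes (7.43%), where chance gives 5.71%. For Dgkb in endothelial-like cells the adjusted p was 0.196, 0.252 and 0.183 without flox control 1, 2 and 3, and 0.0928, 0.0665 and 0.156 without knockout 2, 3 and 4. It was 0.689 when each cell was assigned to a class on its own (log2 fold change -1.94), and the range over all alternatives was 3.08e-08 to 0.832.

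Most genes of mitochondrial respiration were higher in knockout endothelial-like cells, but the call of the list depended on the preset correlation of camera. Of 54 oxidative phosphorylation genes, 50 were higher in knockouts, with a median log2 fold change of 0.43, and 17 had an unadjusted p under 0.05, all higher. The mean of the list was 6.19, 6.33 and 6.687 log2 CPM in flox controls 1, 2 and 3. Knockouts 1, 2, 3 and 4 had 6.701, 6.734, 6.642 and 7.044, so flox control 3 lay above knockout 3. Examples were Atp5g3, a subunit of ATP synthase (0.79, SE 0.21), Ndufb10 and Ndufa6 of complex I (0.89 and 0.74) and Cox7c of cytochrome c oxidase (0.78). Higher values were also found for 75 of 78 ribosomal protein genes (median 0.27), among them Rps15a (0.50) and Rpl27a (0.48), and for all 12 mitochondrially encoded genes (median 0.355), among them mt-Nd3 (0.45) and mt-Nd1 (0.42). The median mitochondrial share of UMIs per kept cell, over all classes, was 4.19%, 4.67% and 7.47% in flox controls 1, 2 and 3 and 6.15%, 5.63%, 7.02% and 6.07% in knockouts 1, 2, 3 and 4. Among endothelial-like cells it was 4.78%, 6.63% and 9.07% against 7.18%, 7.90%, 7.54% and 9.90%. Log2 fold change in this class went with gene length, at a Spearman correlation across genes of -0.369 with gene span, and 75 of 83 other genes than Dgkb that span at least 500 kb were lower in knockouts. Genes are not independent replicates. Interferon response genes were higher for 23 of 24 members (median 0.79), with examples in the interferon-induced Xaf1 (0.97), the immunoproteasome subunit Psmb8 (0.94) and the guanylate-binding protein Gbp4 (1.16). Smooth muscle contraction genes were lower for 17 of 18 members (median -0.65), with examples in the potassium channel Kcnma1 (-2.22), Tagln (-0.67), Synpo2 (-0.78) and the myosin kinase Mylk (-0.63), all of which had their highest level in smooth muscle-like cells. Tagln in endothelial-like cells had 0.016 when each cell was assigned to a class on its own, and Mylk in endothelial-like cells 0.21 with the stricter cell filter. None of these genes passed over all genes tested, and adjusted over the list alone only Kcnma1 passed, whose log2 fold change was -1.5 without flox control 1 (Kcnma1 in endothelial-like cells). With camera at a preset correlation the adjusted p was 4.06e-10 for oxidative phosphorylation, 1.64e-05 for ribosomal proteins, 0.00085 for mitochondrially encoded genes, 0.00171 for smooth muscle contraction and 0.00245 for interferon response, and each had an adjusted p = 0.911 with an estimated correlation. Interferon response in endothelial-like cells rested on knockout 4, whose mean was 7.20 log2 CPM against 5.21 to 5.99 in the other libraries, and Gbp4 in endothelial-like cells had a log2 fold change of 0.27 without it. Without knockout 4 its adjusted p was 0.569, that of smooth muscle contraction in endothelial-like cells 0.182 and that of ribosomal proteins in endothelial-like cells 0.151. Without flox control 1 the adjusted p was 0.639 for interferon response and for ribosomal proteins and 0.334 for smooth muscle contraction and for mitochondrially encoded in endothelial-like cells.

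Gene groups closest to the function of Slc38a2 and of the endothelium went both ways. Of the other amino acid transporters 4 of 9 were higher and 5 lower in knockouts, with Slc3a2, the heavy chain shared by several transporters, at 0.43 and Slc38a6 at -0.49 (0.13 without flox control 2). Genes of the ATF4 response to amino acid shortage were higher for 9 of 15 members, among them Wars, a tryptophan tRNA synthetase (1.29), and Gdf15 (0.97). Wars stood at 72.0 CPM in knockout 4, while the other knockouts, at 19.6 to 22.4 CPM, lay within the flox controls at 12.9 to 27.8 CPM. By contrast, Atf4 itself was lower (-0.50), as was Cebpb (-0.83, but 0.33 without flox control 1). Nitric oxide signalling, which relaxes the vessel, had 12 higher and 11 lower members. Among them were Gch1, needed for the synthase cofactor (0.68), and Pde5a, which degrades cyclic GMP and was highest in smooth muscle-like cells (-1.32). The median of that list was 0.03 and its mean -0.06. Edn1, which encodes the vasoconstrictor endothelin 1, stood at 992 ± 109 CPM in flox controls and 642 ± 76.0 CPM in knockouts without overlap (log2 fold change -0.63, SE 0.20, adjusted p = 0.690). Of the 14 vasoactive factors, 8 were higher and 6 lower, with the adrenomedullin receptor component Ramp2 at 0.66. Endothelial activation genes were lower for 16 of 23 members, such as the adhesion molecule Icam1 (-0.47, but 0.0646 without flox control 3), with a median of -0.10 and a mean of 0.02. None of the 5 lists passed with camera, at adjusted p of 0.983 for the transporters, nitric oxide signalling and vasoactive factors, 0.666 for ATF4 and 0.415 for activation. Without flox control 2, endothelial activation and leukocyte adhesion in endothelial-like cells had an adjusted p of 0.0295 at the preset correlation. The other 20 lists tested had adjusted p of 0.0855 to 0.983, and among their members Rptor, lower in knockouts, passed adjusted over the list alone.

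Smooth muscle-like cells, the contractile wall of the vessel, had 0 genes past edgeR's test out of 12636, with 554 at an unadjusted p under 0.05, where 631.8 would be so by chance, and 9 by DESeq2. The smallest adjusted p, 0.290, belonged to Camk1d, a calcium/calmodulin-dependent kinase, at 70.0 ± 14.3 CPM in flox controls (n = 3) and 32.5 ± 3.77 CPM in knockouts (n = 4). Traf5, an adaptor of tumour necrosis factor receptors, stood at 36.4 ± 4.16 and 58.3 ± 3.23 CPM (adjusted p = 0.327). Also higher in knockouts, at adjusted p of 0.955, were Fcf1 (0.60), the ribonucleotide reductase subunit Rrm2b (0.66), the splicing factor subunit Sf3b6 (0.38), Tmem258 (0.55) and Cpeb1 (1.16), which binds the polyadenylation element of mRNAs. Lower in knockouts were Cmss1 (-1.56), the gephyrin gene Gphn (-0.67) and the Mediator kinase Cdk8 (-0.42). By DESeq2 the adjusted p was 1.06e-05 for Camk1d in smooth muscle-like cells, within a range of 1.06e-05 to 1.00 over its alternatives. Non-overlapping groups were found for 5.19% of genes, where chance gives 5.71%.

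Oxidative phosphorylation genes were higher in knockouts for 51 of 55 members in smooth muscle-like cells (median 0.175), such as Cox7c (0.53), Cox6b1 (0.38) and Cox7b (0.37). So were 67 of 78 ribosomal protein genes (median 0.11), such as Rpl27a (0.28), and 12 of 13 mitochondrially encoded genes (median 0.21), such as mt-Nd2 (0.33). The correlation across genes of log2 fold change with gene span was -0.271 in this class. Macrophage inflammation genes were lower for 16 of 17 members (median -1.01), among them the chemokine Ccl4 (-2.68), the cytokine gene Tnf (-1.87) and Gpnmb (-1.38). Lower values were also found for 22 of 24 genes of activation and leukocyte adhesion (median -0.40), among them the NF-kB subunits Relb (-0.40) and Nfkb1 (-0.53), Birc3 (-0.39) and the cytokine Il6 (-1.01). Il6 in smooth muscle-like cells had 0.13 when each cell was assigned to a class on its own. Ccl4, Tnf, Relb, Nfkb1 and Birc3 had their highest level in macrophage-like cells, and Gpnmb and Il6 in fibroblast-like cells. In smooth muscle-like cells of flox controls Ccl4 and Tnf stood at 15.7 ± 17.6 and 3.15 ± 2.85 CPM. Flox control 1 held the highest values, and without it the log2 fold change was -1.07 for Ccl4 in smooth muscle-like cells, -0.69 for Tnf in smooth muscle-like cells and -0.61 for Gpnmb in smooth muscle-like cells. The contraction genes themselves split into 14 higher and 16 lower of 30 (adjusted p = 0.790, camera). No member passed, either over all genes or adjusted over the list alone. At the preset correlation of camera the adjusted p was 4.12e-08, 4.54e-05, 0.000308, 0.00725 and 0.00503 for the 5 lists in the order given, and each had an adjusted p = 0.901 with an estimated correlation. The other 25 lists had adjusted p of 0.296 to 0.856. Without flox control 1 all 5 calls were lost, with adjusted p of 0.121 for oxidative phosphorylation in smooth muscle-like cells, 0.792 for ribosomal proteins in smooth muscle-like cells, 0.590 for mitochondrially encoded in smooth muscle-like cells and for macrophage inflammation in smooth muscle-like cells, and 0.717 for endothelial activation and leukocyte adhesion in smooth muscle-like cells. Without flox control 3, knockout 1 and knockout 2 the inflammation and activation calls were also lost, with adjusted p of 0.208, 0.187 and 0.237 for inflammation and 0.208, 0.187 and 0.129 for activation, and ribosomal proteins had 0.235 without flox control 2 and 0.10 without knockout 4.

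Fibroblast-like cells, which lay down the matrix of the outer wall, had 0 of 15294 genes past edgeR's test, with 691 at an unadjusted p under 0.05, where 764.7 would be so by chance, and 5 by DESeq2. The 10 genes with the smallest p all had an adjusted p of 0.958. Col8a1, a short-chain collagen of vessel walls, stood at 74.6 ± 3.91 CPM in flox controls (n = 3) and 119.5 ± 12.6 CPM in knockouts (n = 4), and passed when adjusted over the collagen list alone. Other higher values belonged to Slc41a3 (0.50), Sf3b6 (0.50), Cnep1r1 (0.50), AI413582 (0.46) and Cpeb1 (1.19). Lower values belonged to Cyp51, an enzyme of cholesterol synthesis (-0.63), Etl4 (-0.60), Pdzrn3 (-0.55) and Cmss1 (-1.48). Non-overlapping groups were found for 5.78% of genes, close to the 5.71% of chance. By DESeq2 the adjusted p was 0.00373 for Col8a1 in fibroblast-like cells, within a range of 0.00373 to 1.00 over its alternatives.

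In fibroblast-like cells 50 of 55 oxidative phosphorylation genes (median 0.205) and 75 of 79 ribosomal protein genes (median 0.21) were higher in knockouts, for example Cox7c (0.59), Ndufa6 (0.51), Atp5g3 (0.37) and Rpl37 (0.32). The correlation across genes of log2 fold change with gene span was -0.23. Smooth muscle contraction genes were lower for 28 of 30 members (median -0.57), for example Myl9 (-0.58), Csrp1 (-0.40), Cnn1 (-1.51) and the smooth muscle coactivator Myocd (-1.06), and these 4 had their highest level in smooth muscle-like cells. Cnn1 in fibroblast-like cells had -0.90 without flox control 1. Genes of the ATF4 amino acid response were lower for 26 of 32 members (median -0.21), for example Cebpb (-0.51), the alanine transaminase Gpt2 (-0.49), the stress sensor Sesn2 (-0.69) and Fgf21 (-0.99). Collagen and matrix genes split into 24 higher and 20 lower. With camera the adjusted p was 3.45e-10 for the first pair of lists, 1.41e-06 for contraction and 0.0267 for ATF4, and each had an adjusted p = 0.995 with an estimated correlation. Apart from Col8a1, no member of the described lists passed, either over all genes or adjusted over the list alone, and the other 27 lists had adjusted p of 0.0637 to 0.991. ATF4 and amino acid response in fibroblast-like cells turned to higher without flox control 3 (adjusted p = 0.848), and its adjusted p was 0.542 without knockout 4 and 0.644 without the cluster led by Il6, a setting chosen after seeing the data. With genes of other classes left out, smooth muscle contraction in fibroblast-like cells had an adjusted p of 0.304.

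Macrophage-like cells had 0 of 10631 genes past edgeR's test, with 770 at an unadjusted p under 0.05, where 531.6 would be so by chance, and 2 by DESeq2. Other splits of the same libraries gave up to 963 genes at that p. Cpeb1 was read at 39.6 ± 4.78 CPM in flox controls (n = 3) and 160.8 ± 73.1 CPM in knockouts (n = 4), and Wfdc17, a small protein of activated macrophages, at 216.8 ± 73.7 and 464 ± 45.9 CPM. Further higher values belonged to Cystm1 (1.37), the chaperone subunit Pfdn1 (0.84) and the complex I genes Ndufa1 (0.76) and Ndufc1 (0.99). Lower values belonged to the laminin gene Lama2 (-1.34), Cmss1 (-1.43), the non-muscle myosin Myh10 (-0.82) and Prr14l (-0.95). Lama2 had its highest level in fibroblast-like cells, and Myh10, Cystm1, Pfdn1, Ndufa1 and Ndufc1 had theirs in smooth muscle-like cells. Cmss1 overlapped between the groups, at 42.65 CPM in flox control 3 against 32.47 to 51.96 CPM in knockouts. All 10 genes had an adjusted p of 0.669. Without knockout 4, Cpeb1 in macrophage-like cells had an adjusted p of 0.00503, and over its alternatives the range was 1.15e-05 to 0.984. Non-overlapping groups were found for 9.52% of genes, where chance gives 5.71%.

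Macrophage-like cells of knockouts had higher values for 53 of 54 oxidative phosphorylation genes (median 0.34), such as Ndufa1, Cox6c (0.74), Sdhd of complex II (0.74) and Atp5g3 (0.57), and 9 of them passed adjusted over the list alone. Across genes, log2 fold change correlated with gene span at -0.326 in this class. Genes of resident and repair macrophages were higher for 15 of 18 members (median 0.40), such as the chemokine Ccl24 (0.77), Retnla (1.07) and the lectins Cd209g (1.00) and Cd209f (1.01). Lower values were found for 17 of 23 macrophage inflammation genes (median -0.51), such as Ccl5 (-2.51), Ptgs2 (-1.23) and Il6 (-1.26), the last pair highest in fibroblast-like cells, and for 21 of 22 genes of activation and leukocyte adhesion (median -0.41), such as Nfkb1 (-0.68). Interferon response genes were lower for 21 of 29 members (median -0.16), such as Isg15 (-1.64), Rsad2 (-2.56), Ifih1 (-1.42) and Cxcl10 (-1.74). Stress genes were also lower, with 19 of 28 NRF2 targets (median -0.265), such as the cystine transporter Slc7a11 (-1.75). So were 13 of 18 hypoxia genes (median -0.19), such as the glucose transporter Slc2a1 (-1.03), highest in smooth muscle-like cells. Collagen and matrix genes were lower for 39 of 43 members (median -0.61), such as Col3a1 (-0.98) and Col5a1 (-1.02), both highest in fibroblast-like cells. Lower too were 21 of 24 growth factor beta genes (median -0.36), such as Tgfb3 (-1.11), highest in fibroblast-like cells. The same held for 22 of 27 contraction genes (median -0.36), such as Myocd (-1.24), highest in smooth muscle-like cells, and 14 of 18 genes of endothelial to mesenchymal transition (median -0.37). With camera the adjusted p was 1.82e-13 for oxidative phosphorylation, 0.000457 for residency and repair, 0.000341 for collagen, 0.000519 for activation, 0.0108 for growth factor beta, 0.0158 for contraction, 0.0199 for interferon and 0.0457 for the remaining 4, and all 11 had an adjusted p = 0.774 with an estimated correlation. The other 19 lists had adjusted p of 0.0515 to 0.918.

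Calls in macrophage-like cells depended on single libraries. Flox control 3, with 148 macrophage-like cells, had a mean of 6.39 log2 CPM for the interferon genes against 4.82 to 5.31 in the other libraries. Without flox control 3 the direction turned to higher for interferon response in macrophage-like cells (adjusted p = 0.858), for oxidative stress and NRF2 targets in macrophage-like cells (0.858) and for macrophage inflammation in macrophage-like cells (0.806). Of the example genes, without that library Ccl5 in macrophage-like cells had a log2 fold change of 0.77, Rsad2 in macrophage-like cells 0.18, Cxcl10 in macrophage-like cells 0.03, Ptgs2 in macrophage-like cells -0.13, Ifih1 in macrophage-like cells -0.28, Isg15 in macrophage-like cells -0.44, Slc7a11 in macrophage-like cells -0.54 and Il6 in macrophage-like cells -0.65. The call was also lost for endothelial activation and leukocyte adhesion in macrophage-like cells (0.325). Without flox control 1 it was lost for collagen and matrix in macrophage-like cells (0.931), where Col5a1 in macrophage-like cells had a log2 fold change of -0.37, for smooth muscle contraction in macrophage-like cells (0.725), for endothelial to mesenchymal transition in macrophage-like cells (0.508), for hypoxia response in macrophage-like cells (0.266) and for growth factor beta and fibrosis signalling in macrophage-like cells (0.0783). Endothelial to mesenchymal transition, hypoxia and contraction were lost without further libraries, the first with adjusted p of 0.116, 0.115 and 0.352 without flox control 3, knockout 2 and knockout 4, the hypoxia list with 0.230, 0.134 and 0.101 without flox control 3, knockout 1 and knockout 4, and contraction with 0.0542 and 0.618 without knockout 2 and 4. Inflammation had 0.274 and 0.153 without knockout 1 and 4, the NRF2 targets 0.127, 0.0542 and 0.101 without knockout 1, 2 and 4, and interferon response 0.0781 and 0.0923 without knockout 2 and 3. Oxidative phosphorylation and the genes of residency and repair passed without any single library, at adjusted p of at most 1.49e-06 for oxidative phosphorylation in macrophage-like cells and 0.0247 for macrophage residency and repair in macrophage-like cells. Both calls were lost with an estimated correlation (adjusted p = 0.774).

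**Figure D2:**
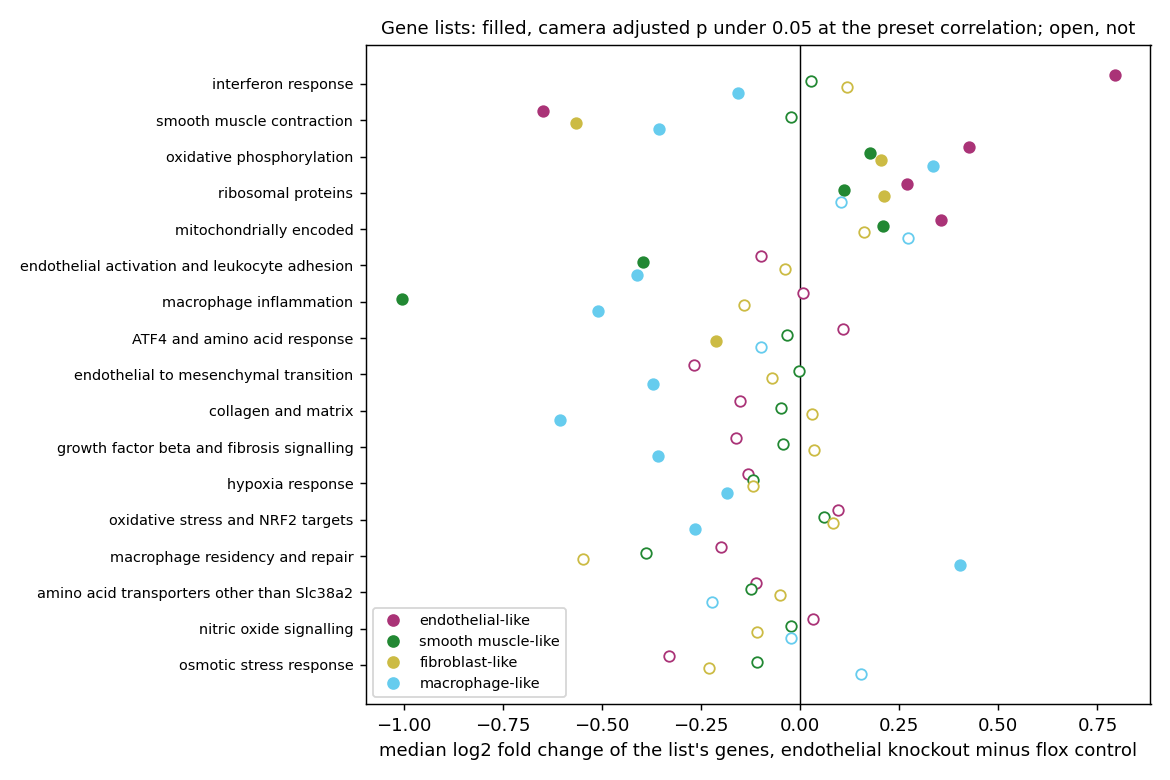
Median log2 fold change, knockout against flox control, of the described gene lists other than the vasoactive factors (vertical axis) in the 4 main cell classes. Each point is the median over the tested genes of a list. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation and open points those without, and oxidative phosphorylation had a median of 0.175 to 0.43 in all 4 classes, and smooth muscle contraction had its lowest median, -0.65, in endothelial-like cells.

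Whether the genotype acted differently on endothelial-like and smooth muscle-like cells was tested directly, with both classes of each library in 1 model. Dgkb was the 1 gene out of 10833 whose change differed, lower by a log2 difference of -4.19 (SE 0.55, adjusted p = 0.00761, edgeR) in endothelial-like cells. In smooth muscle-like cells Dgkb stood at 82.9 ± 8.74 CPM in flox controls (n = 3) and 66.8 ± 9.28 CPM in knockouts (n = 4), a log2 fold change of -0.30. For Slc38a2 the difference between the classes was -0.34 (SE 0.239) and did not pass (adjusted p = 1.00). The count was 0 without flox control 2 and without flox control 3, and 4 without knockout 4. With the low count filter left off it was 25 genes.

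The make-up of the aorta varied widely between libraries of the same genotype. Fibroblast-like cells made up 52.5% ± 6.01 (SD, n = 3) of kept cells in flox controls and 54.2% ± 11.8 (SD, n = 4) in knockouts, and smooth muscle-like cells 26.9% ± 7.51 and 24.9% ± 14.7. Macrophage-like cells made up 5.21% ± 2.29 and 6.06% ± 1.77. Endothelial-like cells made up 1.20% ± 0.297 in flox controls and 3.04% ± 3.29 in knockouts, where knockout 4 held 7.87% and knockout 1 held 0.472%. That library, knockout 4, also had the lowest share of smooth muscle-like cells, 4.84%. Schwann-like cells, the glia of peripheral nerves, had 0.205% ± 0.0522 and 0.0833% ± 0.0663, and monocyte-like and neutrophil-like cells 0.203% ± 0.0675 and 0.115% ± 0.00814 in flox controls against 0.982% ± 0.922 and 0.510% ± 0.531 in knockouts. The monocyte-like share was 1.406% and 2.082% in knockouts 1 and 4 against 0.2417% and 0.1986% in knockouts 2 and 3. The neutrophil-like share was 1.276% in knockout 1 against 0.1159% to 0.458% in the other knockouts. T cell-like cells had 0.671% ± 0.276 and 1.185% ± 1.28, B cell-like cells 0.163% ± 0.157 and 0.382% ± 0.397, mast cell-like cells 0.248% ± 0.0808 and 0.576% ± 0.714, and erythroid-like cells 0.375% ± 0.155 and 0.716% ± 0.963. Knockout 4 held 0.9575% B cell-like cells, against 0.06621% to 0.3122% in the other knockouts. In exact two-sided permutation tests 0 of 11 classes passed, with an adjusted p of 0.914 for each and unadjusted p of 0.0857 for Schwann-like and 0.571 for endothelial-like cells. With 35 splits the smallest p is 0.0286, which a class that reached it alone would carry to an adjusted p of 0.314. The digestion and viability staining that preceded capture can set these shares.

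**Figure D3:**
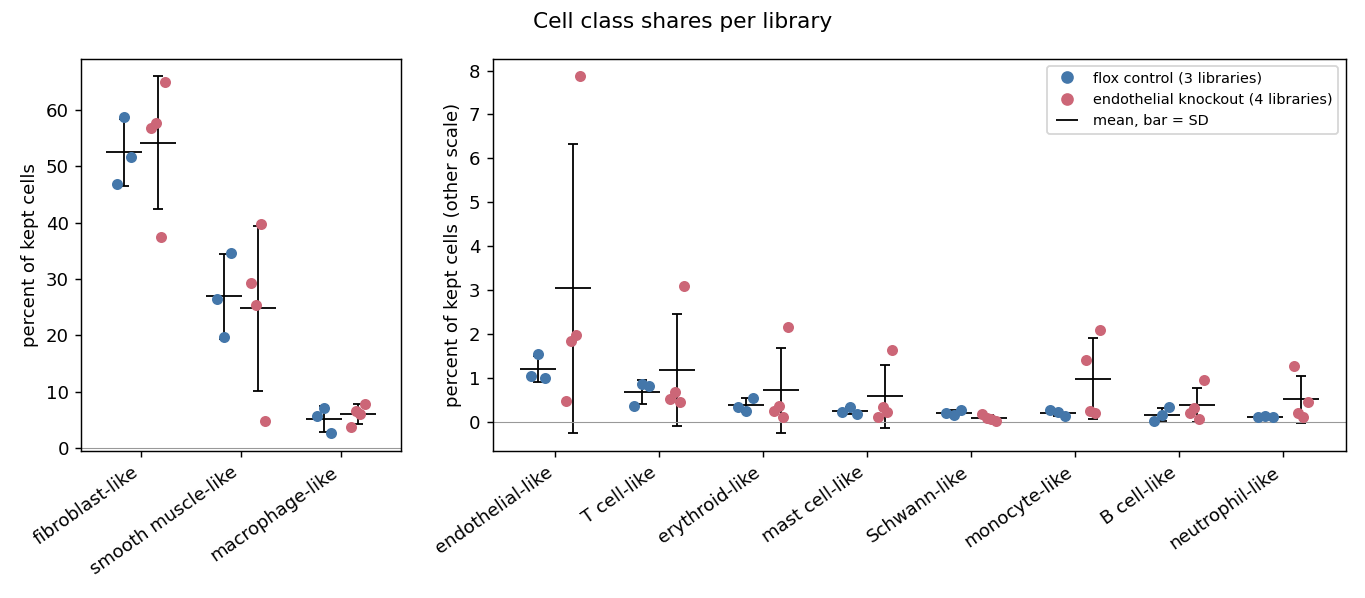
Share of kept cells, in percent on linear axes, of the 11 named cell classes, with 1 point per library and mean ± SD bars for 3 flox control and 4 endothelial knockout libraries. The fibroblast-like, smooth muscle-like and macrophage-like classes have their own axis, and knockout 4 stands at 4.84% smooth muscle-like and 7.87% endothelial-like cells.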

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

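The counts over other splits of the libraries for single genes in endothelial-like cells were chosen after the result was seen. The smooth muscle RNA, gene length and interaction tests of Dgkb had their predictions written before those values were seen.

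Dgkb stood out because its genotype effect differed between cell classes, with an endothelial-like log2 change lower by -4.19 than the smooth muscle-like one, in the test of the difference itself. RNA leaking from smooth muscle-like cells, where Dgkb is higher, could give such UMIs. The median contraction gene in endothelial-like cells of flox controls had 0.0872 of its smooth muscle-like level (18 genes, upper quartile 0.131, highest 1.05) against 0.437 for Dgkb. That argues against a leak in proportion to the typical contraction gene as the whole source. It cannot speak for genes that leak in other proportions. In knockout endothelial-like cells 17 of the 18 contraction genes were also lower (median log2 fold change -0.65), so smooth muscle RNA stays open as a part of the fall. A lower yield of long genes is also argued against as the whole cause, since the 83 other genes spanning at least 500 kb had a median log2 fold change of -0.41 (SD 0.45, lowest -2.22), although 75 of them were lower. Chance could not be excluded, since 7 of the 35 splits of the libraries gave as many interaction genes (real 1, highest other 4) and 6 gave as many genes in endothelial-like cells (real 1, highest other 3). Dgkb was also lower at an unadjusted p under 0.05 in macrophage-like (log2 fold change -1.24), fibroblast-like (-0.73) and smooth muscle-like cells (-0.30). Beside chance and smooth muscle RNA, both an effect in endothelial cells and a difference between whole libraries thus stay open, on endothelial-like sums with at most 22 UMIs of Dgkb each.

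The following values lay apart from the other 3 knockout libraries by Dixon's test, which was applied to 177 groups of values and marks about 1 in 20 by chance. Knockout 4 held 3.09% T cell-like, 2.15% erythroid-like and 1.64% mast cell-like cells, where the others held 0.439% to 0.685%, 0.108% to 0.363% and 0.111% to 0.332%. Endothelial-like cells of knockout 4 had 2830 CPM of Cd74, the invariant chain of antigen presentation (others 38.2 to 160), 276 of Gbp4 (46.6 to 82.2), 255 of Psmb8 (86.5 to 106), 72.0 of Wars (19.6 to 22.4) and 12400 of mt-Co2 (9030 to 9600). In the same class knockout 2 had 65.7 CPM of Serpina1b (others 120 to 123) and 23.8 of Slc38a6 (12.7 to 14.3), and knockout 3 had 67.5 of Ndufb10 (79.9 to 82.0). Smooth muscle-like cells had 62.1 CPM of Rrm2b in knockout 4 (others 98.9 to 103), 1060 of Rpl27a in knockout 4 (886 to 909) and 19900 of mt-Nd2 in knockout 2 (18300 to 18500). Col8a1 stood at 138 CPM in fibroblast-like cells of knockout 3 (others 110 to 115).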

How the results depend on the processing

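Leaving out the libraries with under 100 endothelial-like cells, and the fibroblast-like cluster led by Il6, were alternatives chosen after seeing the data. On simulated data 25% of 2-fold changes were recovered in endothelial-like cells, so most changes of that size would be missed there, and smaller ones were not simulated. Slc38a2 in endothelial-like cells stayed lower and short of the threshold in all 16 alternatives, at log2 fold changes of -0.54 to -0.29 and adjusted p of 0.534 to 1.00. Cell class shares gave 0 calls throughout, which says nothing about stability, since 1 class at the smallest p that 35 splits allow would have an adjusted p of 0.314. Of the values that answer a comparison, 97 stayed within 1.5 times or on their side of the threshold and 53 moved. Of all other values 2946 stayed the same, 40 came to pass, 118 no longer passed and 54 changed direction. These tallies do not measure stability, since a count of 0 that stayed 0 was taken as the same. So was a value short of the threshold that kept its direction and again fell short. Of the named genes only Dgkb in endothelial-like cells passed in the main setting, and no share did. Where no construction is named below, the cause was not tested.

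For genes changed in endothelial-like cells the count of 1 became 68 with no low count filter, 2 with DESeq2, and 0 with the stricter cell filter, doublets kept, classes per cell or the libraries with under 100 endothelial-like cells left out. Leave-one-out gave 0 to 1, with 0 without every library but knockout 1. For genes changed in smooth muscle-like cells the count of 0 became 7 with no low count filter, 9 with DESeq2 and 0 to 3 in leave-one-out. For genes changed in fibroblast-like cells it became 5 with DESeq2 and 0 to 5 in leave-one-out, and for genes changed in macrophage-like cells 43 with no low count filter, 2 with DESeq2 and 0 to 1 in leave-one-out. In these 3 classes the upper value, 3, 5 and 1, came without knockout 4. For genes whose genotype effect differs between endothelial-like and smooth muscle-like cells the count of 1 became 25 with no low count filter and 0 to 4 in leave-one-out (0 without flox control 2 or 3, 4 without knockout 4), and limma-voom gave 1.

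For gene lists changed in endothelial-like cells (5), gene lists changed in smooth muscle-like cells (5), gene lists changed in fibroblast-like cells (4) and gene lists changed in macrophage-like cells (11) the count was 0 with the estimated gene correlation and 0 with fry. Without genes of other classes it was 3 in smooth muscle-like and 5 in macrophage-like cells, with fewer genes tested. With the libraries with under 100 endothelial-like cells left out, 8 lists were called in endothelial-like cells. Leave-one-out gave 1 to 8 in endothelial-like cells (1, 8 and 3 without flox control 1, flox control 2 and knockout 4) and 0 to 6 in smooth muscle-like cells (0 without flox control 1, 3 without flox control 3, knockout 1 or knockout 2). It gave 4 to 9 in fibroblast-like cells (9, 8 and 7 without flox control 3, knockout 1 and knockout 2) and 6 to 13 in macrophage-like cells (6 without flox control 1 or knockout 4, 7 without knockout 2).

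Changed directions among lists are given as adjusted p. For amino acid transporters other than Slc38a2 in endothelial-like cells it was 0.983 with fry, 0.995 without genes of other classes, 0.598 with the libraries with under 100 endothelial-like cells left out and 0.705 to 0.944 in leave-one-out (turned without flox control 3 and knockout 1, 2 or 4). For endothelial vasoactive factors in endothelial-like cells it was 0.983 with fry, 0.995 without genes of other classes and 0.552 to 0.982 in leave-one-out (turned without flox control 1 and knockout 2, 3 or 4). For endothelial activation and leukocyte adhesion in endothelial-like cells it was 0.215 with the libraries with under 100 endothelial-like cells left out and 0.0295 to 0.820 in leave-one-out (turned without flox control 3, 0.780). In leave-one-out nitric oxide signalling in endothelial-like cells had 0.705 to 0.983 (turned without flox control 2 or knockout 4) and ATF4 and amino acid response in endothelial-like cells 0.526 to 0.972 (turned without knockout 2, 0.847). Without flox control 3 the direction turned at the upper end of the range for ATF4 and amino acid response in fibroblast-like cells (0.000437 to 0.848), interferon response in macrophage-like cells (2.13e-05 to 0.858), oxidative stress and NRF2 targets in macrophage-like cells (0.00607 to 0.858) and macrophage inflammation in macrophage-like cells (0.00451 to 0.806).

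Changed directions among genes are given as log2 fold changes. With classes per cell the values were 0.016 for Tagln in endothelial-like cells, 0.0066 for Il1b in macrophage-like cells and 0.13 for Il6 in smooth muscle-like cells, and with the stricter cell filter 0.21 for Mylk in endothelial-like cells. With the libraries with under 100 endothelial-like cells left out they were 0.25 for Icam1 in endothelial-like cells and 0.13 for Ptgs2 in endothelial-like cells. Leave-one-out gave -1.29 to 4.31 for Cd74 in endothelial-like cells (lowest without knockout 4). The highest value came without flox control 1 for Cebpb in endothelial-like cells (-1.42 to 0.33) and Nfkb1 in endothelial-like cells (-0.68 to 0.0235), and without flox control 2 for Slc38a6 in endothelial-like cells (-0.83 to 0.13). It came without flox control 3 for Icam1 in endothelial-like cells (-0.79 to 0.0646), Ccl5 in macrophage-like cells (-3.11 to 0.77), Cxcl10 in macrophage-like cells (-2.25 to 0.0281), Rsad2 in macrophage-like cells (-3.21 to 0.18) and Slc38a2 in smooth muscle-like cells (-0.24 to 0.0999).

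Changed directions among shares are given as knockout minus flox control, in percentage points or on the log ratio scale. The share of fibroblast-like cells had -1.40 with classes per cell, and with the centred log ratio -0.194, where the share of macrophage-like cells had -0.0186 and the share of erythroid-like cells -0.147. Among immune cells alone the share of macrophage-like cells had -10.6 and the share of T cell-like cells -1.06. Without knockout 4 the direction turned for the share of fibroblast-like cells (-1.81 to 7.34 in leave-one-out), the share of T cell-like cells (-0.122 to 0.763), the share of erythroid-like cells (-0.138 to 0.543), the share of mast cell-like cells (-0.0263 to 0.483) and the share of smooth muscle-like cells (-7.06 to 4.58). It also turned without flox control 1 for fibroblast-like cells (-1.04), without flox control 3 for smooth muscle-like cells (1.76) and without flox control 3 for the share of macrophage-like cells (-0.404 to 1.84).

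Whether the replicate numbers pair the libraries stays open, since the labels do not say so and the correlations do not settle it. Deviations of same-numbered libraries correlated across genes at 0.177, -0.059 and 0.004 in endothelial-like cells, 0.139, 0.174 and 0.046 in smooth muscle-like cells, 0.146, 0.021 and 0.219 in fibroblast-like cells and 0.25, -0.08 and 0.112 in macrophage-like cells. Differently numbered libraries ranged from -0.245 to 0.313, -0.171 to 0.128, -0.271 to 0.212 and -0.272 to 0.182 in these classes. With the replicate block the count was 0 for genes changed in endothelial-like cells, 4 for genes changed in smooth muscle-like cells, 7 for genes changed in fibroblast-like cells and 1 for genes changed in macrophage-like cells. The block gave 2 gene lists changed in endothelial-like cells, and turned the direction of amino acid transporters other than Slc38a2 in endothelial-like cells (adjusted p = 0.968, 0.598 to 0.995 over the alternatives named above), of endothelial vasoactive factors in endothelial-like cells (0.968) and of Cd74 in endothelial-like cells (log2 fold change -0.63).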

Other observations

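The counts over other splits for genes and gene lists within a class, and the comparison of Slc38a2 between classes, were tests chosen after the results were seen, and so was the set of genes that moved the same way in all 4 main classes.

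Of 6977 genes tested in all 4 main classes, 15 moved the same way in each with an unadjusted p under 0.05. The 11 higher in knockouts included the respiratory chain genes Ndufc1, Ndufc2, Ndufa12, Cox6b1, Cox7c and Cox17, the hypoxia-inducible family member Higd2a, the vesicle tethering gene Trappc1, the ribonucleotide reductase subunit Rrm2b and the near-identical ribonuclease genes Rnaset2a and Rnaset2b, which can share reads. Cox7c had log2 fold changes of 0.78, 0.53, 0.59 and 0.67 in endothelial-like, smooth muscle-like, fibroblast-like and macrophage-like cells, and Rrm2b 0.72, 0.66, 0.67 and 0.68. The 4 lower in knockouts were Cmss1 (-1.72, -1.56, -1.48 and -1.43), Slc5a3 (-0.89, -0.64, -0.76 and -0.75), Sash1 (-0.65, -0.45, -0.57 and -0.61) and Dgkb. The fall of Cmss1 rested on flox controls 1 and 2, at 974.9 and 1196 CPM in endothelial-like cells. Flox control 3 lay within the knockouts in endothelial-like (299.7 CPM against 135.4 to 372.8) and macrophage-like cells (42.65 against 32.47 to 51.96). It lay little above their highest value in smooth muscle-like (153.8 against 131) and fibroblast-like cells (105.8 against 103.6). Slc5a3 encodes a sodium-coupled transporter of myo-inositol, an osmolyte that cells take up in hypertonic surroundings. The osmotic stress list as a whole did not pass in endothelial-like cells, with 6 genes higher and 10 lower (median log2 fold change -0.33, adjusted p = 0.30, camera).

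Fibroblast-like cells fell into clusters whose shares of kept cells varied between libraries of a genotype. The largest made up 12.9% ± 3.29 (SD, n = 3) in flox controls and 16.9% ± 9.44 (SD, n = 4) in knockouts, and the cluster led by Il6, Cxcl1, Ptgs2 and Lif 11.1% ± 8.69 and 9.50% ± 5.94, with 21.1% in flox control 3. Unnamed clusters were kept out of the classes by a rule set after the data were seen. The unnamed cluster led by Dmd and Ctnna3 made up 8.33% ± 7.32 in flox controls and 3.64% ± 3.82 in knockouts, that led by Enpp2, Chad and Rgs5 2.58% ± 2.06 and 2.15% ± 1.36, that led by Lyz1, H2-Eb1 and Cd74 0.838% ± 0.342 and 1.10% ± 0.909, and that led by Car3, Adipoq and Mmrn1 0.434% ± 0.135 and 0.491% ± 0.187. These shares were not tested between genotypes. The last of these clusters, with 327 cells, scored best on lymphatic endothelial markers but held more top genes of another class. Its cells are therefore not among the endothelial-like cells. The stricter cell filter named a further endothelial-like cluster of 182 cells led by Fabp4, Cd36 and Flt1, and a lymphatic endothelial-like cluster of 74 cells. Assigned per cell, 774 unnamed cells fell in the endothelial-like class. These alternatives thus change which endothelial cells are included.

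The genes that moved together in all 4 classes may reflect a difference between whole libraries rather than the endothelial knockout, whose effect on the whole vessel wall also stays open. Chance could not be excluded, since 7 of the 35 splits of the libraries gave as many such genes (real 15, highest other 82). The split with 82 set flox controls 1 and 2 and knockout 1 apart, so it followed genotype in part. Whether it reflects a structure of the samples apart from genotype was not tested. Passenger alleles on 1 linked segment are argued against for the set as a whole, since 26.7% of the 15 genes, namely Cox17, Cmss1, Rnaset2a and Rnaset2b, lay within 20 Mb of another of them. Gene length stays open and cannot be told apart from genotype here, because the Spearman correlation across genes of log2 fold change and gene span was -0.369, -0.271, -0.23 and -0.326 in endothelial-like, smooth muscle-like, fibroblast-like and macrophage-like cells. The bound set for gene length as the cause, below -0.3 in all 4 classes, was passed in 2 of them, no class came within the bound against it, and genes are not independent replicates.

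Slc38a2 was lower in each knockout library than in every flox control in endothelial-like cells, and a loss in endothelial cells only was tested as an explanation. The endothelial-like change minus the smooth muscle-like one was -0.34 (SE 0.239, adjusted p = 1.00 in edgeR's interaction test), so these classes cannot be told apart. In endothelial-like cells the log2 fold change was -0.40 (SE 0.22). Those in macrophage-like (-0.43, SE 0.21) and fibroblast-like cells (-0.39, SE 0.27) differed from it by less than their SE. None of these changes passed the test, so they cannot decide for or against a loss in endothelial cells only. The spread between libraries and the unknown position of the reads relative to the deleted exons keep that explanation open.

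For the counts of gene lists called within a class, chance could not be excluded in any class. As many gene lists were called in 24 of the 35 splits in endothelial-like cells (real 5, highest other 9), 24 in smooth muscle-like cells (real 5, highest other 15), 33 in fibroblast-like cells (real 4, highest other 17) and 9 in macrophage-like cells (real 11, highest other 16). For single genes in smooth muscle-like, fibroblast-like and macrophage-like cells the real count was 0, which all 35 splits reach by construction, so the splits test nothing there. The highest other count was 68, 5 and 2 in these classes. The split with 68 genes set flox control 3, knockout 3 and knockout 4 apart, which may reflect a structure of the samples apart from genotype that was not tested. It also called 15 lists, as did the split that set flox control 2, knockout 1 and knockout 2 apart.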
